A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

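RNA from 12 cultures was measured, 4 independent clones of each of 3 yeast strains ([isp-], [ISP+] and sfp1delta), and each culture has its own array. Per the labels' protocols, cells were grown in YPD to an optical density of 0.4, total RNA was extracted and labelled with Cy3, and it was hybridised to Agilent yeast expression arrays. The deposited scanner files give intensity values that Agilent Feature Extraction 10.10.1.1 made from 1-colour scans, per the file headers. Their processed signal has the local background subtracted and spatial and multiplicative trends within the array removed, per the file headers, and is not normalized between arrays. The raw mean signal of a spot and the median of its local background, also intensity values per the file headers, were used only for the normexp alternative. The authors also deposited a matrix of log2 values with 1 value per probe, and limma 3.10.3 is listed, per the submitters' processing notes, without a stated role. Columns of that matrix have medians of 10.487 to 10.513 and correlate with the log2 scanner signal of the same array at 0.976 to 0.994, with slopes of 0.935 to 1.17 over the brighter probes. At the 5th, 25th, 50th, 75th and 95th percentiles the columns differ by 0.0417 at most, against 0.574 to 3.12 for the log2 scanner signal. It is thus on a log2 scale, keeps the direction of the signal and has nearly the same distribution in every column, and how that was reached is unknown. It served as an alternative only.

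Each array holds 12512 non-control spots, 2 for each of 6256 probes, which represent 6225 genes. Spots flagged as outliers (4.86% to 10.5% per array) were left out, and 0 spots were saturated. The log2 processed signal was averaged over the 2 spots of a probe, and the 75th percentile of each array over non-control probes was subtracted. For the 29 genes with more than 1 probe the probe with the highest mean signal was used. Genes well above background on at least 4 of the 12 arrays were tested, which kept 5918 and left out 307. Both spots were flagged for 1518 gene values, which were treated as missing in the fits to single genes (among named genes on 1 or 2 arrays of at least 1 strain for ARG1, RPS9A, HSP26, PUT1, AGX1, COR1, FLR1, FUR4, RPN2, SEI1, ERG6, NDI1, HXK2, GPP2, ECM4 and GTT2), and 9 genes have no estimate in at least 1 strain. The camera tests, the correlations between arrays, the correlations with split [isp-] arrays and the screen for arrays that stood out used the flagged spots' signal for these values. Gene names are those of a reference table where it gave one, and otherwise those of the array design. The table also gave the synonyms used to match list members and the gene lengths. It held 5591 of the tested genes, and the other 327 kept the design's name and have no length or match. The tested genes include 372 dubious open reading frames and 2 transposon genes, which are described only by count, and 127 genes whose probe lists more than 1 gene. Deletion, prion and difference calls among the dubious frames were 112 up and 49 down, 16 and 38, and 60 and 116, and 1 transposon gene was called in each comparison.

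Comparisons were made with R 4.3.3 and limma 3.58.1, using lmFit and eBayes on the log2 values, with statmod 1.5.0 for random blocks, version 1.17.8 of the R package data.table for reading files and matplotlib 3.10.9 for figures. The 3 strains entered a single fit so that they share an estimate of the spread of each gene, and 3 contrasts were tested two-sided. Every adjusted p for a gene is limma's moderated test with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Where a strain was not well above background on all 4 arrays and the other strain was, only a bound is given as "at least N-fold". It sets the brighter strain's mean against the dimmer strain's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. Exact two-sided permutation tests over the 70 splits of 8 arrays were used for SFP1 and for chromosome medians, and 0.0286 is the smallest p they can give. The number of arrays limits the precision. In simulated data with 100 changed genes of each size, the fit recovered 33% of changes of 0.5 and 75% of changes of 1 on the log2 scale for sfp1delta against [isp-]. It recovered 28% and 73% for [ISP+] against [isp-] and 27% and 68% for [ISP+] against sfp1delta, with 7, 4 and 3 false calls (6.09%, 3.81% and 3.06% of calls). Far fewer genes changed there than were called in the data (62.2%, 21.7% and 64.0%), which makes the adjusted threshold stricter. Every simulated array also had the pooled spread, to which sfp1delta replicate 3 adds. The recovered shares therefore do not give the recovery in these data.

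The 31 gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. Lists cover cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation initiation and elongation, translation termination and nonsense-mediated decay, aminoacyl-tRNA synthetases, chaperones and the Msn2 and Msn4 stress response. They also cover methionine and sulphate assimilation, amino acid synthesis under Gcn4, purine and one-carbon metabolism, phosphate under Pho4, iron under Aft1, glycolysis, the TCA cycle, glucose-repressed genes, hexose transport, the cell cycle, histones, ergosterol, the proteasome and the cell wall. The remaining lists hold mating, sporulation, nitrogen catabolite repression, seripauperin and COS genes, regulators of ribosomal genes, prion proteins and modifiers, nutritional marker genes and the mitochondrial genome. Each list was set against all other genes with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists, and again with the correlation estimated. The directional test of limma's fry, which asks only whether a list's own genes changed, was run too, with the same adjustment. The rule named SFP1, SUP35, SUP45 and HSP104 always, the 10 largest rises and 10 largest falls per comparison among called genes whose 4 arrays of a strain all lay above the 4 of the other, up to 4 members per list with the smallest adjusted p, up to 5 genes per kind of overlap, and the neighbours of SFP1. RPS9B, SIR2, GRE2, IZH4, RTA1, ECM4, GTT2, ARO9, ARO10, AGA2, BAR1, SAG1 and MATALPHA1 lie outside the rule and were chosen after their values were seen. Genes whose 4 arrays of the strains did not overlap made up 59.2%, 47.6% and 59.6% of those tested in the 3 comparisons, against 2.86% by chance.

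Arrays lay on 2 slides, 8 on the first ([isp-] replicates 2, 3 and 4, sfp1delta 2 and 3, [ISP+] 1, 2 and 3) and 4 on the other ([isp-] 1, sfp1delta 1 and 4, [ISP+] 4), where only the 2 sfp1delta arrays give a spread, and the slide was tested as a fixed and a random block and each slide alone. For the relation of the prion and deletion effects, which share the [isp-] arrays, unchanged groups were simulated 100 times and the [isp-] arrays were also split. Alternatives fixed in advance were quantile normalization, centring on the array median or on 7 spike-in probes, normexp background correction with an offset of 50 followed by quantile normalization, and the authors' values. Others were no filter on dim probes, a filter on all 12 arrays, the mean of a gene's probes, flagged spots kept, the slide settings, the slide row or the clone number as a block, a fit to the 2 strains compared, eBayes with trend and robust options, array weights, thresholds of 0.01 or of 2-fold, an estimated correlation in camera, ribosomal genes without their A or B copy, and each array left out in turn. Leaving out the genes of chromosomes II and IX, removing each chromosome's median from each array, and removing a trend on gene length (lowess with a span of 0.4) were added after the data were seen.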

Results

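Transcript levels were measured in 3 related strains of budding yeast, Saccharomyces cerevisiae, grown in rich glucose medium and harvested during growth. SFP1 encodes Sfp1p, a zinc-finger transcription factor that activates genes for ribosomal proteins and ribosome assembly. The [isp-] strain carries SFP1 without the prion, and the sfp1delta strain lacks the gene. The [ISP+] strain carries the prion form of Sfp1p, a protein state inherited through the cytoplasm. Each strain was represented by 4 clones, each with its own Cy3-labelled 1-colour array, which makes 12 arrays. The 75th percentile of the signal was 3454, 4094, 3943 and 4429 scanner units on the [isp-] arrays. It was 5614, 3705, 7562 and 4359 units on the sfp1delta arrays and 3181, 3497, 3476 and 3082.5 units on the [ISP+] arrays, each in replicate order. Between 89.6% and 97.9% of the probes lay well above background on an array, and 5918 genes were tested. Correlations across genes between arrays of the same strain were 0.9946 to 0.9974 in [isp-] and 0.9915 to 0.9964 in [ISP+]. In sfp1delta they were 0.9288 to 0.9966, and replicate 3 gave the low values.

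SFP1 (YLR403W, chromosome XII, 925568 to 927619, Genome Release 64-1-1) was the targeted gene, and its probe lies inside the coding sequence at 927335 to 927394. Relative to each array's 75th percentile, its log2 level was -1.53, -1.86, -1.46 and -1.58 on the 4 [isp-] arrays and -1.73, -1.48, -1.57 and -1.52 on the 4 [ISP+] arrays. On the sfp1delta arrays it was -10.2, -10.5, -8.50 and -7.92. There, neither spot of replicates 1 and 2 and only 1 of the 2 spots of replicates 3 and 4 lay well above background. The strain means were -1.61 ± 0.18 in [isp-], -1.57 ± 0.11 in [ISP+] and -9.29 ± 1.28 in sfp1delta (SD, n = 4 each). SFP1 signal was at least 140-fold lower in sfp1delta than in [isp-] (limma adjusted p = 1.01e-07), with all 4 sfp1delta arrays below all 8 others. The exact two-sided permutation p was 0.0286, the smallest that 4 arrays against 4 can give. Between [ISP+] and [isp-] the SFP1 transcript did not differ detectably (log2 fold change 0.03, adjusted p = 0.97, exact permutation p = 0.714).

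**Figure D1:**
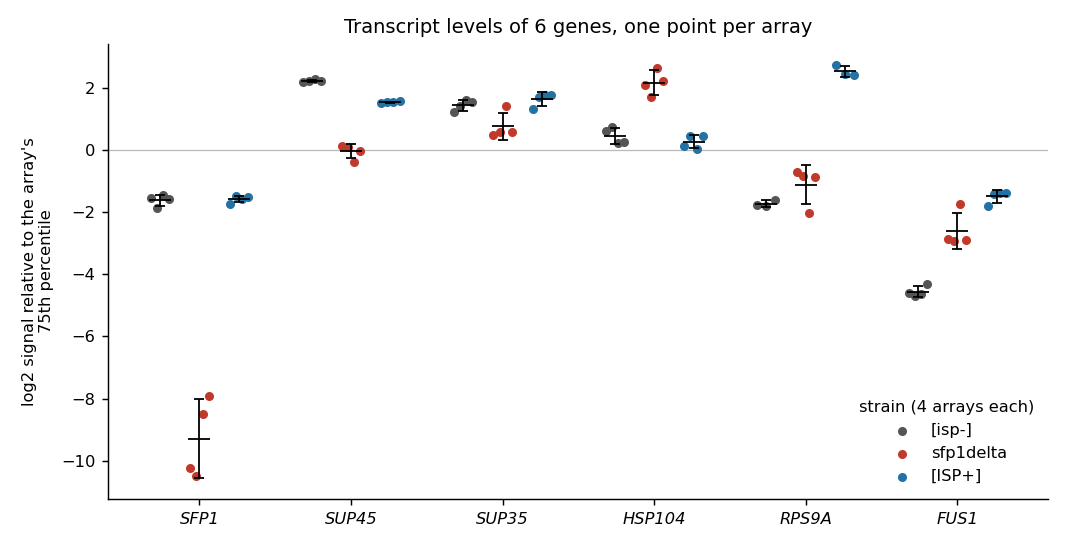
Log2 signal relative to the array's 75th percentile for 6 genes in the 3 strains, with a point for each array with a value. A black bar gives the mean and SD of 4 arrays, or of 3 for RPS9A in [isp-] and in [ISP+]. SFP1 lies at -1.61 in [isp-], -1.57 in [ISP+] and -9.29 in sfp1delta, and SUP45 lies at 2.23 in [isp-], -0.04 in sfp1delta and 1.54 in [ISP+].

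The first comparison, sfp1delta against [isp-], asked what the loss of SFP1 does to transcription. Genes of the translation machinery fell, and genes of respiration, stress and the use of poor carbon and nitrogen sources rose (adjusted p = 0.472 for the TCA cycle and 0.114 for the nitrogen list with an estimated correlation). The 136 cytosolic ribosomal protein genes had a median log2 fold change of -1.37 and the 154 ribosome biogenesis genes one of -1.16 (adjusted p = 0.40 and 0.114 with an estimated correlation). The 58 stress genes driven by Msn2 and Msn4 had a median of 1.70 and the 38 glucose-repressed genes one of 2.39 (adjusted p = 0.122 and 0.196 with an estimated correlation). PCK1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, rose by 5.37 (SE 0.33, adjusted p = 1.15e-07), and HXT2, a hexose transporter, by 5.20 (SE 0.18, adjusted p = 2.13e-09; 4 arrays per strain). IMD2, an IMP dehydrogenase of GTP synthesis, fell by 4.13 (SE 0.18, adjusted p = 9.39e-09).

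Among the ribosomal protein genes, 0 rose, 130 fell and 6 were not called. Their median was -1.37 (adjusted p = 4.81e-21, and adjusted p = 0.40 with an estimated correlation), and adjusted over the list alone 0 rose and 132 fell. RPL18B changed by -3.11, RPL7B by -2.67 and RPL22B by -2.25, and the list's median was -1.70 within the slide of 8 arrays and -1.154 within the slide of 4, which holds 1 [isp-], 1 [ISP+] and 2 sfp1delta arrays. Relative to the [isp-] mean, the list lay at -2.58 on sfp1delta replicate 3 and -0.90 on replicate 2, both on the slide of 8. It lay at -1.005 on both sfp1delta arrays of the slide of 4. Ribosome biogenesis genes make and modify ribosomal RNA and assemble the subunits, and of these 0 rose, 145 fell and 9 were not called. The median was -1.16 (adjusted p = 9.82e-33, and adjusted p = 0.114 with an estimated correlation), and 0 rose and 145 fell when adjusted over the list alone. UTP25 on chromosome IX, whose genes had a median of -0.59 as a whole, changed by -2.39. BFR2 changed by -1.48 and GAR1 by -1.46, with a list median of -1.22 and -0.99 within the 2 slides. RNA polymerases I and III transcribe ribosomal and transfer RNA, and of their 35 listed genes 4 rose, 26 fell and 5 were not called, with RPA135 at -2.02 and RPA43 at -1.38. Adjusted over the list alone, 5 rose and 26 fell, at a median of -0.83 (adjusted p = 5.21e-06, and adjusted p = 0.114 with an estimated correlation). Translation initiation and elongation factors included the initiation factor subunits PRT1 at -1.82 and NIP1 at -1.79, and 1 rose, 36 fell and 3 were not called. Their median was -1.11 (adjusted p = 3.17e-12, and adjusted p = 0.114 with an estimated correlation), and adjusted over the list alone 1 rose and 36 fell. Of 21 aminoacyl-tRNA synthetase genes, which charge transfer RNA, 0 rose, 19 fell and 2 were not called, and ILS1 on chromosome II changed by -2.22 (-1.46 with each chromosome's median removed) and SES1 by -1.52. The median was -1.61 (adjusted p = 2.16e-11, and adjusted p = 0.201 with an estimated correlation), and 0 rose and 19 fell when adjusted over the list alone.

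Biosynthetic pathways moved with the translation genes. Of 58 amino acid synthesis genes under Gcn4, 2 rose, 39 fell and 17 were not called. Their median was -0.77 (adjusted p = 5.47e-10, and adjusted p = 0.259 with an estimated correlation), and adjusted over the list alone 2 rose and 40 fell. ILV3 of the branched-chain pathway changed by -2.74 and LEU9 of leucine synthesis by -2.34. Of 25 purine and one-carbon genes, 0 rose, 24 fell and 1 was not called, with IMD3 at -2.45 and the serine hydroxymethyltransferase gene SHM2 at -2.29. The median was -1.20 (adjusted p = 4.56e-11, and adjusted p = 0.147 with an estimated correlation), and 0 rose and 24 fell when adjusted over the list alone. Other large falls were those of the CTP synthase gene URA7 at -3.61 (SE 0.32), the ATPase gene OLA1 at -3.26 (SE 0.12) and the S-phase cyclin gene CLB6 at -3.25 (SE 0.12). URA7 and OLA1 lie on chromosome II, whose genes had lower signal as a whole, and with each chromosome's median removed they changed by -2.85 and -2.50. SNO1, a gene of vitamin B6 metabolism, changed by -3.11 (SE 0.26), OSI1 by -3.56 and YAR075W by -3.54. BSC1 was at least 6.66-fold lower and was not well above background on all sfp1delta arrays.

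Genes that glucose normally represses rose. Of 38 gluconeogenic and other glucose-repressed genes, 33 rose, 2 fell and 3 were not called, among them the fructose bisphosphatase gene FBP1 at 4.55 and POT1 on chromosome IX, a thiolase of fatty acid oxidation, at 3.54 (4.14 with each chromosome's median removed). Their median was 2.39 (adjusted p = 4.04e-10, and adjusted p = 0.196 with an estimated correlation), and adjusted over the list alone 33 rose and 2 fell. The succinate-fumarate carrier gene SFC1 rose by 5.57 (SE 0.38). All 18 measured hexose transport genes rose, including HXT5 at 4.11 and the repressor gene MIG3 at 2.02. The median was 1.85 (adjusted p = 2.14e-07, and adjusted p = 0.114 with an estimated correlation), and 18 rose and 0 fell when adjusted over the list alone. Of 54 TCA cycle and respiration genes, 44 rose, 0 fell and 10 were not called, with the lactate dehydrogenase gene CYB2 at 2.89 and the NADH dehydrogenase gene NDI1 at 1.97. Adjusted over the list alone, 45 rose and 0 fell, at a median of 0.92 (adjusted p = 1.03e-06, and adjusted p = 0.472 with an estimated correlation).

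Stress genes under Msn2 and Msn4 followed, of which 51 rose, 3 fell and 4 were not called. Their median was 1.70 (adjusted p = 4.86e-11, and adjusted p = 0.122 with an estimated correlation), and adjusted over the list alone 52 rose and 3 fell. The list's median was 1.97 within the slide of 8 arrays and 1.41 within the slide of 4. Relative to the [isp-] mean, it was 2.25 on sfp1delta replicate 3 and 1.62 on replicate 2, both on the slide of 8. On the sfp1delta arrays of the slide of 4 it was 1.47 and 1.55. DDR2 rose by 4.13, MSN4 itself by 3.31 and the glycogen synthase gene GSY1 by 5.06 (SE 0.35). The small heat shock protein gene HSP26 on chromosome II rose by 5.01 (SE 0.38, measured on 2 [isp-] arrays; 5.76 with each chromosome's median removed). Of 43 cell wall genes, 27 rose, 6 fell and 10 were not called, with the glucan synthase gene GSC2 at 5.08 (SE 0.15) and the wall protein gene PIR3 at 2.46. The median was 0.92 (adjusted p = 0.00118, and adjusted p = 0.237 with an estimated correlation), and 27 rose and 6 fell when adjusted over the list alone. Of 32 genes under nitrogen catabolite repression, 20 rose, 4 fell and 8 were not called, with the general amino acid permease gene GAP1 at 3.18 and the ammonium permease gene MEP2 at 1.85. Their median was 0.92 (adjusted p = 0.00174, and adjusted p = 0.114 with an estimated correlation), and adjusted over the list alone 20 rose and 4 fell. Of 35 seripauperin and subtelomeric COS genes, 30 rose, 1 fell and 4 were not called, and 23 of these probes list several near-identical genes. Adjusted over the list alone, 31 rose and 1 fell, at a median of 1.43 (adjusted p = 6.28e-08, and adjusted p = 0.136 with an estimated correlation). Of 27 sporulation genes, 18 rose, 1 fell and 8 were not called, with the meiotic regulator gene NDT80 at 2.12. The median was 1.19 (adjusted p = 0.00195, and adjusted p = 0.258 with an estimated correlation), and 18 rose and 1 fell when adjusted over the list alone. After quantile normalization the sporulation list was not called (adjusted p = 0.342). Of 39 mating genes, 22 rose, 1 fell and 16 were not called, and the a-factor gene MFA1 rose by 4.67. Their median was 0.48 (adjusted p = 0.00603, and adjusted p = 0.114 with an estimated correlation), and adjusted over the list alone 22 rose and 1 fell.

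Several lists went both ways. Of 36 proteasome genes 2 rose, 14 fell and 20 were not called. The median was -0.30 (adjusted p = 0.00174, and adjusted p = 0.472 with an estimated correlation), and 1 rose and 9 fell when adjusted over the list alone. The proteasome call was lost after quantile normalization (adjusted p = 0.409), the median became 0.44 after centring on the spike-ins, and it was -0.20 without sfp1delta replicate 3. Of 47 chaperone genes 13 rose, 20 fell and 14 were not called, the same adjusted over the list alone, and their median of -0.11 and mean of 0.05 differ in sign (adjusted p = 0.156). SSA4, a stress-induced Hsp70, rose by 3.42 and SSB1, a ribosome-bound Hsp70, changed by -2.37. Of 28 iron genes under Aft1 16 rose, 6 fell and 6 were not called, the same adjusted over the list alone, with the ferroxidase gene FET3 at 2.72 and the low-affinity transporter gene FET4 at -2.62. The iron list was not called by camera (median 0.67, adjusted p = 0.212), though fry's directional test called it higher (adjusted p = 0.0268). Of 27 glycolytic genes 5 rose, 11 fell and 11 were not called, the same adjusted over the list alone (median -0.47, adjusted p = 0.154), with the pyruvate kinase gene PYK2 at 2.09 and the hexokinase gene HXK2 at -1.29. Without sfp1delta replicate 3 the glycolysis median was -0.19.

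HSP104 (chromosome XII, 88623 to 91349), the disaggregase that most yeast prions need for their inheritance, rose from 0.46 ± 0.26 to 2.17 ± 0.40 (SD, n = 4 each). That was a log2 fold change of 1.71 (SE 0.20, adjusted p = 1.41e-05). SUP45 (chromosome II, 530869 to 532182), which encodes translation release factor eRF1, went from 2.23 ± 0.04 to -0.04 ± 0.23, a change of -2.27 (SE 0.11, adjusted p = 1.95e-08; -1.51 with each chromosome's median removed). SUP35 (chromosome IV, 808324 to 810381), which encodes eRF3, went from 1.44 ± 0.17 to 0.77 ± 0.43, a change of -0.68 (SE 0.20, adjusted p = 0.00965). With spike-in centring the SUP35 change was 0.05. Near SFP1 on chromosome XII, RPL31B changed by -1.102 (adjusted p = 0.00111), and the 136 ribosomal protein genes it belongs to had a median of -1.37. DUS4 changed by -0.55 (adjusted p = 0.00688), or by 0.18 with spike-in centring, and DUS3 was not called (0.25, adjusted p = 0.134). SEI1, directly beside SFP1, was called higher at 0.27 (adjusted p = 0.0336). That call was lost without [isp-] replicate 1, 3 or 4 or sfp1delta replicate 1 or 2 (adjusted p = 0.0768, 0.0792, 0.0614, 0.0706 and 0.0931), and the value was -0.18 in the authors' values.

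In all, 3677 of 5910 genes (62.2%) changed, 2191 up and 1486 down, of which 881 and 679 changed at least 2-fold. With the slide as a fixed block the count was 3682, and within the slide of 8 arrays it was 3245. No count is given for the slide of 4, where [isp-] has a single array. Whether rises or falls were more numerous depended on the scaling. The median of all genes was 0.16, against -0.02 with quantile normalization and 0.88 with spike-in centring. Replicate 3 of sfp1delta stood apart from the other 3 arrays in several of these lists. Without it the median was -0.97 for ribosomal proteins, 1.17 for the TCA cycle list, 2.21 for the glucose-repressed list and 1.64 for hexose transport. Of the 31 lists, 9 rose and 10 fell past the threshold at camera's preset correlation of 0.01, and 0 of the 19 did so with an estimated correlation. In fry's directional test only mitochondrial ribosomal proteins among the 19 were not past it (adjusted p = 0.293), and cytosolic ribosomal proteins had adjusted p = 0.00216.

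**Figure D2:**
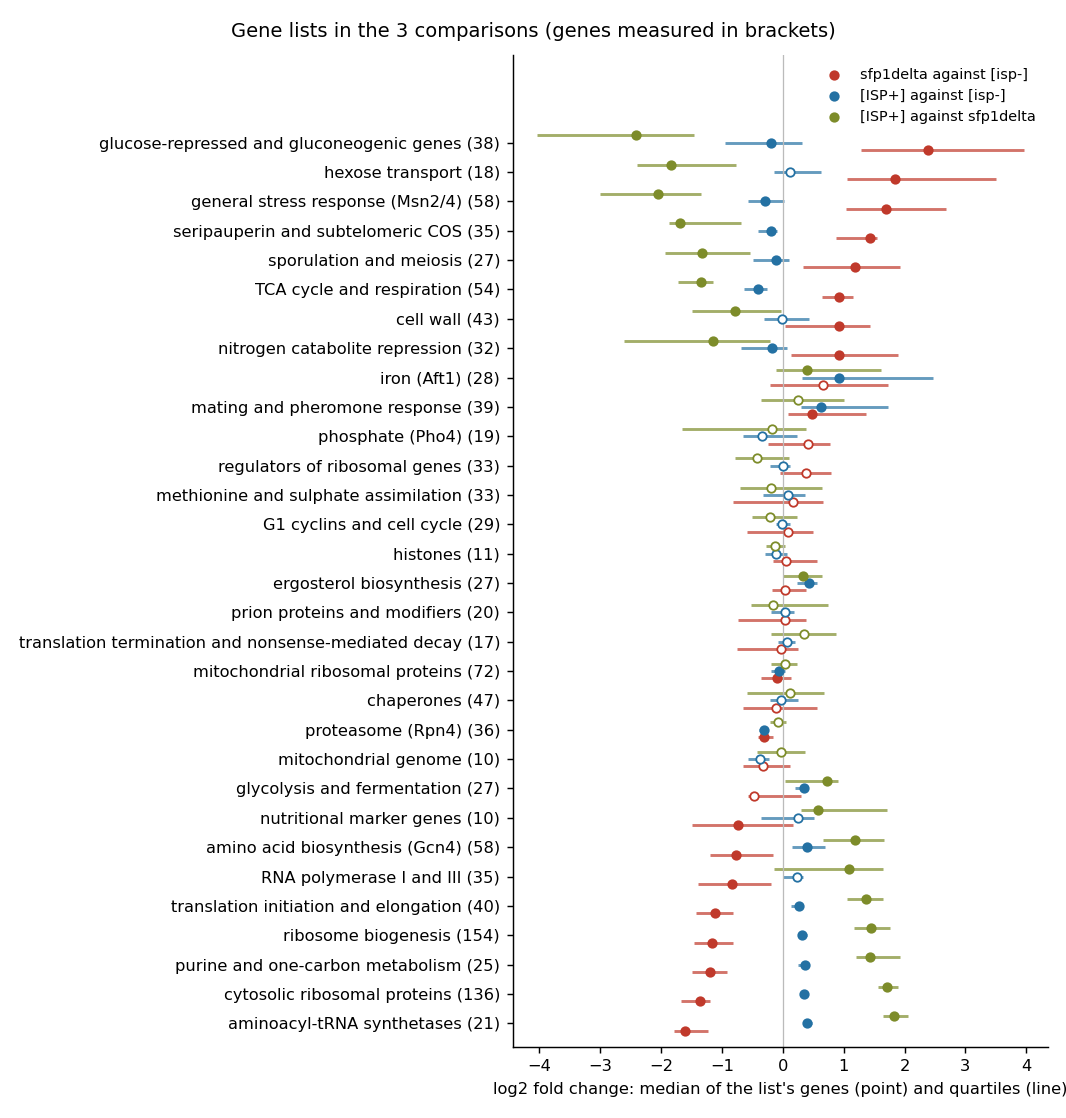
Median log2 fold change (points, filled where camera's adjusted p was under 0.05) and quartiles (lines) of the genes in 31 lists in the 3 comparisons. Ribosomal proteins lie at -1.37 in sfp1delta and 0.35 in [ISP+] against [isp-], and the glucose-repressed list lies at 2.39 and -0.19.

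Both comparisons against [isp-] showed 2 whole chromosomes with lower signal. In [ISP+], the median log2 fold change relative to the other chromosomes was -0.98 for the 412 genes on chromosome II and -0.94 for the 207 genes on chromosome IX, or 1.98-fold and 1.92-fold lower. In sfp1delta the same values were -0.96 and -0.82. Between [ISP+] and sfp1delta they were 0.01 for chromosome II and -0.16 for chromosome IX. In [ISP+], 95.6% of the genes on II and 95.2% of those on IX lay below the median of the other chromosomes. The lower signal extended over both arms, with -0.98 and -0.99 on the left and right arm of II and -0.92 and -1.001 on those of IX in [ISP+]. In sfp1delta the arms had -0.97, -0.96, -0.87 and -0.50 in the same order. Relative medians of the other 14 chromosomes lay between -0.08 and 0.19 in sfp1delta and between -0.04 and 0.05 in [ISP+]. All 4 arrays of either strain lay below all 4 [isp-] arrays on both chromosomes. The exact two-sided permutation p was 0.0286, the smallest possible, and 0.0653 after Benjamini-Hochberg adjustment over 48 tests. Within the slide of 8 arrays and the slide of 4, the values in [ISP+] were -0.99 and -0.95 for II and -0.93 and -0.92 for IX. In sfp1delta they were -1.02 and -0.96 for II and -0.76 and -0.83 for IX.

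**Figure D3:**
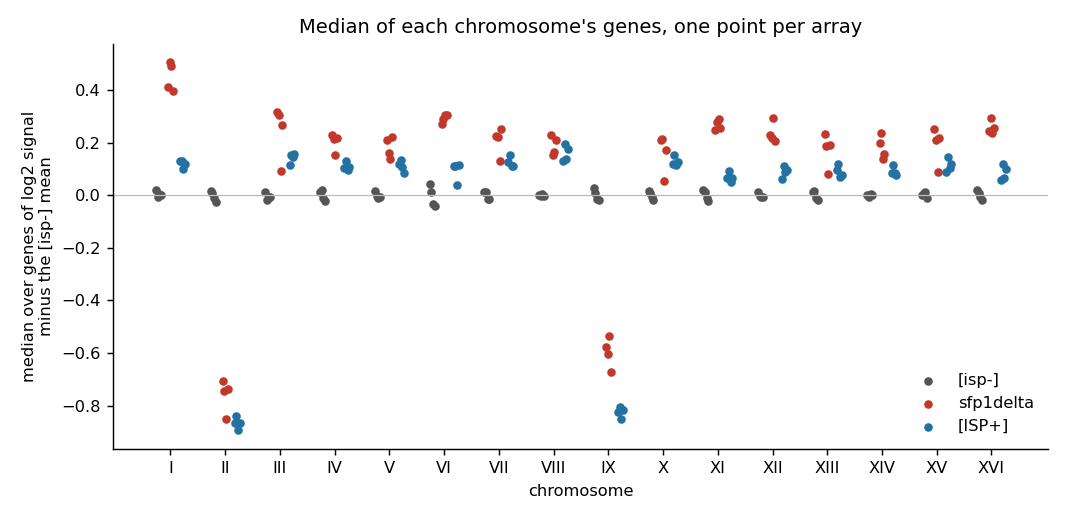
Median over each chromosome's genes of the log2 signal minus the [isp-] mean, with a point for each array, for 16 chromosomes and 3 strains. Relative to the other chromosomes, chromosome II lies at -0.98 in [ISP+] and -0.96 in sfp1delta and chromosome IX at -0.94 and -0.82, while the rest differ by 0.19 at most.

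The second comparison, [ISP+] against [isp-], asked which transcripts differ when Sfp1p is in its prion state. Pheromone response and iron uptake genes rose (adjusted p = 0.00125 and 0.523 with an estimated correlation), and genes on chromosomes II and IX made up most of the falls. The cell fusion gene FUS1 went from -4.56 ± 0.18 to -1.48 ± 0.21 (SD, n = 4 each), a log2 fold change of 3.08 (SE 0.24, adjusted p = 6.01e-06). RPS9A, 1 of a pair of genes for a ribosomal protein of the small subunit, rose by 4.27 (SE 0.30, adjusted p = 1.06e-05; 3 arrays per strain with a value). FIT2, a cell wall mannoprotein of siderophore iron uptake, rose by 4.62 (SE 0.43, adjusted p = 1.65e-05), and ARG3, ornithine carbamoyltransferase, rose by 2.46 (adjusted p = 2.92e-07).

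Of 39 mating and pheromone response genes, 23 rose, 1 fell and 15 were not called. The list had a median of 0.62 (camera adjusted p = 1.91e-11, and adjusted p = 0.00125 with an estimated correlation), and adjusted over the list alone 25 rose and 1 fell. PRM1, a gene of cell fusion, rose by 2.37 and MFA1 by 2.25. FIG1, on chromosome II with its lower signal, was at least 18.8-fold higher (adjusted p = 2.92e-07), PRM6 at least 10.3-fold (adjusted p = 5.6e-05) and the alpha-factor gene MF(ALPHA)1 at least 8.72-fold (adjusted p = 2.62e-04), since these 3 were not well above background on all [isp-] arrays. The list's median was 0.65 within the slide of 8 arrays and 0.76 within the slide of 4. Of 28 iron genes under Aft1, 19 rose, 1 fell and 8 were not called. Their median was 0.92 (adjusted p = 5.88e-10, and adjusted p = 0.523 with an estimated correlation), and adjusted over the list alone 20 rose and 2 fell. Within the slides the iron median was 0.88 and 1.06. The siderophore transporter gene SIT1 rose by 2.92, FET3 by 2.86, ARN1 by 2.63 and FIT3 by 3.36 (SE 0.56), and ARN2 was at least 12.3-fold higher.

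Of 58 amino acid synthesis genes under Gcn4, 25 rose, 4 fell and 29 were not called, with the arginine gene ARG1 at 2.16 and the histidine gene HIS4 at 0.99. Their median was 0.41 (adjusted p = 8.4e-07, and adjusted p = 0.607 with an estimated correlation), and adjusted over the list alone 28 rose and 5 fell. Of 25 purine and one-carbon genes, 10 rose, 1 fell and 14 were not called, with IMD2 at 0.75 and IMD3 at 0.65. The median was 0.36 (adjusted p = 7.29e-04, and adjusted p = 0.607 with an estimated correlation), and 15 rose and 2 fell when adjusted over the list alone. Of 21 synthetase genes, 10 rose, 1 fell and 10 were not called, with VAS1 at 0.55. Their median was 0.39 (adjusted p = 0.00114, and adjusted p = 0.61 with an estimated correlation), and adjusted over the list alone 15 rose and 3 fell. Of 27 ergosterol genes, 6 rose, 0 fell and 21 were not called, with the HMG-CoA reductase gene HMG1 at 0.79 and ERG6 at 0.71. The median was 0.43 (adjusted p = 1.23e-04, and adjusted p = 0.607 with an estimated correlation), and 8 rose and 0 fell when adjusted over the list alone. Of 154 ribosome biogenesis genes, 31 rose, 5 fell and 118 were not called, and the RNA helicase gene ROK1 rose by 0.58. Adjusted over the list alone, 36 rose and 5 fell, at a median of 0.32 (adjusted p = 9.51e-10, and adjusted p = 0.607 with an estimated correlation). Within the slides the ribosome biogenesis median was 0.27 and 0.53. The 5 ribosome biogenesis falls over all genes were on chromosomes II and IX. So were the 4 Gcn4, 1 purine and 1 synthetase falls. Of 136 ribosomal protein genes, 2 rose, 0 fell and 134 were not called. Their median was 0.35 (adjusted p = 0.00192, and adjusted p = 0.884 with an estimated correlation), and adjusted over the list alone 1 rose and 0 fell. After quantile normalization the ribosomal protein median was 0.17 and the list was not called (adjusted p = 0.162).

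Of 54 TCA cycle and respiration genes, 0 rose, 17 fell and 37 were not called, with KGD1 on chromosome IX at -1.54 and COR1 on chromosome II at -1.38, and 5 of the falls were on these chromosomes. With each chromosome's median removed KGD1 changed by -0.72, and COR1 was not called (-0.52, adjusted p = 0.0552). The median was -0.41 (adjusted p = 2.59e-08, and adjusted p = 0.607 with an estimated correlation), and 0 rose and 18 fell when adjusted over the list alone. Within the slides the TCA cycle median was -0.32 and -0.73. Relative to the [isp-] mean the list lay at -0.03 on [ISP+] replicate 1, inside the range of the [isp-] arrays (-0.12 to 0.13), and at -0.42, -0.62 and -0.57 on the other 3. Of 58 stress genes under Msn2 and Msn4, 3 rose, 11 fell and 44 were not called, with NQM1 at -0.87 and 5 falls on II and IX, which leaves 6 falls elsewhere. Their median was -0.30 (adjusted p = 0.00357, and adjusted p = 0.607 with an estimated correlation), and adjusted over the list alone 4 rose and 11 fell. Of 36 proteasome genes, 0 rose, 13 fell and 23 were not called, with RPN2 on chromosome IX at -1.35 (-0.53 with each chromosome's median removed) and RPN13 at -0.42. The median was -0.31 (adjusted p = 1.51e-08, and adjusted p = 0.57 with an estimated correlation), and 0 rose and 15 fell when adjusted over the list alone. Of 32 nitrogen catabolite genes, 1 rose, 12 fell and 19 were not called, with GAP1 at -0.97 and 7 falls on II and IX. Adjusted over the list alone, 1 rose and 12 fell, at a median of -0.17 (adjusted p = 0.00685, and adjusted p = 0.523 with an estimated correlation). Off II and IX the nitrogen catabolite median was -0.03 (adjusted p = 0.0186).

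Hexose transport, cell wall and chaperone lists were not called. Of 18 hexose transport genes 4 rose, 3 fell and 11 were not called, with HXT4 at 2.65, HXT6 at 2.13 and the repressor gene MIG3 at -1.35. Their median was 0.12 (adjusted p = 0.516), and adjusted over the list alone 5 rose and 3 fell. Of 43 cell wall genes 12 rose, 10 fell and 21 were not called, the same adjusted over the list alone, and the median of -0.01 and mean of 0.18 differ in sign (adjusted p = 0.925). Of 47 chaperone genes 1 rose, 5 fell and 41 were not called, the same adjusted over the list alone (median -0.03, adjusted p = 0.616). HSP104 was not called (-0.19, adjusted p = 0.555) and neither was SUP35 (0.20, adjusted p = 0.531). SUP45 changed by -0.69 (adjusted p = 6.4e-04), and with each chromosome's median removed it differed by 0.18 and was not called (adjusted p = 0.293).

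Of 5909 genes, 1284 (21.7%) changed, 489 up and 795 down. On chromosomes II and IX lay 478 of the falls (60.1%), where 76.8% and 79.2% of the genes fell against 5.99% elsewhere. Among the 10 largest falls were those of OSI1 at -3.20 (SE 0.25), the transcriptional repressor gene XBP1 on IX at -2.78 (SE 0.38), MOH1 on II, which was at least 6.31-fold lower, and ECM13 on II at -2.69 (SE 0.18). The proline oxidase gene PUT1 was at least 5.01-fold lower, YKL070W at least 4.74-fold and the galactose gene GAL7 on II at least 4.90-fold. With each chromosome's median removed XBP1 changed by -1.95, ECM13 by -1.83 and GAL7 by -1.47. The bound for MOH1 includes the lower signal of chromosome II, whose genes had a median of -0.88. Off these chromosomes the phosphatase gene PHM8 changed by -2.27 (adjusted p = 2.29e-05). The count of genes was 1262 with the slide as a fixed block and 730 within the slide of 8 arrays, and the slide of 4 has 1 array of each of these strains. Without sfp1delta replicate 3, whose spread enters the pooled error, it was 2733, with more than 100 rises and 10 falls among the 136 ribosomal protein genes and 107 and 7 in ribosome biogenesis.

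Counts within these lists also moved with other arrays, while the lists' medians and calls held. Without sfp1delta replicate 3, 21 ergosterol, 19 purine and 15 synthetase genes rose and 29 proteasome, 28 stress and 28 TCA cycle genes fell. Of 47 chaperone genes 13 rose and 8 fell without it. Stress gene rises numbered 0 to 1 without [isp-] replicates 2, 3 or 4 or [ISP+] replicates 2, 3 or 4, and ribosomal protein rises numbered 1 without any 1 of the [isp-] or [ISP+] arrays or sfp1delta replicate 1. Ribosome biogenesis rises numbered 11 to 14 without [isp-] replicate 1 or 2 or [ISP+] replicate 3 or 4. Synthetase rises numbered 4 to 5 without any 1 of the [isp-] arrays or of [ISP+] replicates 2 to 4. Purine rises numbered 5 to 6 without any 1 of the [isp-] arrays or [ISP+] replicate 2 or 4. Proteasome falls numbered 5 to 8 without [isp-] replicate 1, 2 or 3 or [ISP+] replicate 2, 3 or 4.

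The third comparison, [ISP+] against sfp1delta, asked how far the prion state departs from loss of the gene. Translation, amino acid and purine synthesis genes were higher in [ISP+], and stress and glucose-repressed genes were lower, calls that were lost with an estimated correlation (adjusted p = 0.125 to 0.323). SFP1 itself was at least 143-fold higher (adjusted p = 6.11e-08). IMD2 was higher by 4.88 (SE 0.18, adjusted p = 1.57e-09), RPL18B by 3.73 (SE 0.20, adjusted p = 2.63e-08) and RPS9A by 3.66 (SE 0.28, adjusted p = 1.96e-06; 3 [ISP+] arrays with a value). PUT1 was at least 110-fold lower (adjusted p = 5.49e-08; 3 sfp1delta arrays with a value), the meiotic gene RIM4 at least 77.4-fold (adjusted p = 6.69e-09) and PCK1 at least 71.6-fold (adjusted p = 1.19e-08).

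Of 136 ribosomal protein genes 135 were higher, 0 lower and 1 was not called. Their median was 1.72 (adjusted p = 1.92e-24, and adjusted p = 0.323 with an estimated correlation), and adjusted over the list alone 135 were higher and 0 lower. Of 154 ribosome biogenesis genes 152 were higher, 0 lower and 2 were not called, with NOP56 at 2.05 and CBF5 at 1.85. The median was 1.45 (adjusted p = 7.01e-38, and adjusted p = 0.125 with an estimated correlation), and 152 were higher and 0 lower when adjusted over the list alone. Within the slides of 8 and 4 arrays the medians were 2.03 and 1.34 for ribosomal proteins and 1.44 and 1.53 for ribosome biogenesis. The slide of 8 holds sfp1delta replicate 3, with a ribosomal protein median of -2.58 relative to the [isp-] mean (other sfp1delta arrays -1.005 to -0.90). Of 21 synthetase genes 21 were higher, 0 lower and 0 were not called. Their median was 1.83 (adjusted p = 6.1e-13, and adjusted p = 0.16 with an estimated correlation), and adjusted over the list alone 21 were higher and 0 lower. Of 40 translation factor genes 36 were higher, 2 lower and 2 were not called, with ANB1 at 2.51. The median was 1.36 (adjusted p = 1.11e-13, and adjusted p = 0.125 with an estimated correlation), and 36 were higher and 2 lower when adjusted over the list alone. Of 35 polymerase genes 23 were higher, 5 lower and 7 were not called. Their median was 1.09 (adjusted p = 1.45e-05, and adjusted p = 0.125 with an estimated correlation), and adjusted over the list alone 24 were higher and 6 lower. Of 25 purine genes 24 were higher, 0 lower and 1 was not called. The median was 1.44 (adjusted p = 1.5e-12, and adjusted p = 0.147 with an estimated correlation), and 24 were higher and 0 lower when adjusted over the list alone. Of 58 Gcn4 genes 47 were higher, 2 lower and 9 were not called, with ARG1 at 3.59 (SE 0.12) and LEU9 at 3.08. Adjusted over the list alone, 47 were higher and 2 lower, at a median of 1.19 (adjusted p = 3.11e-14, and adjusted p = 0.16 with an estimated correlation). Of 28 iron genes 11 were higher, 2 lower and 15 were not called. Their median was 0.40 (adjusted p = 0.00467, and adjusted p = 0.509 with an estimated correlation), and adjusted over the list alone 11 were higher and 2 lower. The iron median was 0.61 without [ISP+] replicate 1 and -0.56 with spike-in centring. Of 39 mating genes 15 were higher, 11 lower and 13 were not called, the same adjusted over the list alone. The mating list was not called by camera (median 0.25, adjusted p = 0.0908), though it was without sfp1delta replicate 3 (median 0.34, adjusted p = 0.0372). In fry's directional test with all arrays it was higher (adjusted p = 0.00318).

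Of 58 stress genes 2 were higher, 52 lower and 4 were not called, with DDR2 at -4.09 and HSP12 at -3.82. The median was -2.05 (adjusted p = 2.03e-12, and adjusted p = 0.131 with an estimated correlation), and 2 were higher and 52 lower when adjusted over the list alone. Of 38 glucose-repressed genes 0 were higher, 34 lower and 4 were not called, with FBP1 at -4.95. Their median was -2.42 (adjusted p = 1.23e-10, and adjusted p = 0.16 with an estimated correlation), and adjusted over the list alone 0 were higher and 34 lower. Within the slides the medians were -2.21 and -1.75 for stress genes and -3.09 and -1.74 for glucose-repressed genes. On sfp1delta replicate 3, on the slide of 8, the glucose-repressed median was 3.37 relative to the [isp-] mean (other sfp1delta arrays 2.15 to 2.23). The stress median there was 2.25 (others 1.47 to 1.62). Of 18 hexose transport genes 1 was higher, 17 lower and 0 were not called. The median was -1.84 (adjusted p = 1.24e-05, and adjusted p = 0.147 with an estimated correlation), and 1 was higher and 17 lower when adjusted over the list alone. Of 54 TCA cycle genes 0 were higher, 52 lower and 2 were not called. Their median was -1.35 (adjusted p = 1.61e-10, and adjusted p = 0.311 with an estimated correlation), and adjusted over the list alone 0 were higher and 52 lower. Of 35 seripauperin and COS genes 0 were higher, 27 lower and 8 were not called. The median was -1.68 (adjusted p = 2.56e-07, and adjusted p = 0.16 with an estimated correlation), and 0 were higher and 27 lower when adjusted over the list alone. Of 32 nitrogen catabolite genes 5 were higher, 22 lower and 5 were not called. Their median was -1.149 (adjusted p = 2.11e-04, and adjusted p = 0.125 with an estimated correlation), with 5 higher and 23 lower adjusted over the list alone. Of 43 cell wall genes 7 were higher, 28 lower and 8 were not called, with GSC2 at -5.16. The median was -0.78 (adjusted p = 0.0017, and adjusted p = 0.216 with an estimated correlation), and 8 were higher and 28 lower when adjusted over the list alone. Of 27 sporulation genes 0 were higher, 20 lower and 7 were not called. Their median was -1.33 (adjusted p = 1.92e-04, and adjusted p = 0.16 with an estimated correlation), and adjusted over the list alone 0 were higher and 20 lower. The sporulation call was lost after quantile normalization (adjusted p = 0.0713).

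XBP1 was lower at -6.50 (SE 0.38), the transporter gene ATO2 at -5.54 (SE 0.29) and the aminotransferase gene AGX1 at -5.51 (SE 0.26). SUP45 was higher by 1.58 (adjusted p = 1.62e-07) and SUP35 by 0.88 (adjusted p = 0.00191; -0.08 with spike-in centring), and HSP104 was lower at -1.90 (adjusted p = 4.91e-06). In all, 3785 of 5916 genes (64.0%) differed, 1554 higher and 2231 lower in [ISP+]. With the slide as a fixed block 3812 differed, and within the slide of 8 arrays 3372 did. The balance of higher and lower genes turned with the scaling. The median of all genes was -0.14, against 0.03 with quantile normalization and -1.09 with spike-in centring. Of the 19 lists past the threshold, 0 stayed past it with an estimated correlation. In fry's directional test only ergosterol among them was not past it (adjusted p = 0.054), and ribosomal proteins had adjusted p = 5.55e-04.

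The prion and deletion effects were then set side by side, to ask whether the prion acts like loss of Sfp1p. Outside chromosomes II and IX they ran against each other more often than together. Of 5293 such genes, 198 rose in both strains (191 for independent lists) and 41 fell in both (65.8). Opposite changes numbered 342, of which 187 were up in sfp1delta and down in [ISP+] (126.7) and 155 the reverse (99.2). PUT1 rose by 4.56 in sfp1delta and was at least 5.01-fold lower in [ISP+], and RIM4 rose by 4.57 and was at least 3.26-fold lower. IMD2 (-4.13 and 0.75) and ARG1 (-1.43 and 2.16) went the other way. MFA1 (4.67 and 2.25) and ARN2 (at least 13.3-fold and 12.3-fold) rose in both, and OSI1 (-3.56 and -3.20) and YKL070W (at least 2.55-fold and 4.74-fold lower) fell in both.

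Across all 5909 genes 560 changed in the same direction, 203 up (181.3 for independent lists) and 357 down (199.8), and 396 in opposite directions. Chromosomes II and IX held 316 of the 357 shared falls, among them the uracil permease gene FUR4 (-2.72 and -1.11), ECM13 (-1.48 and -2.69) and FLR1 (-1.44 and -2.32). With each chromosome's median removed these became -1.97 and -0.25 for FUR4, not called in [ISP+] (adjusted p = 0.218), -0.72 and -1.83 for ECM13, and -0.67 and -1.46 for FLR1. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.06 over all genes and -0.08 off II and IX. The covariance off II and IX was -0.039, against 0.026 for 100 simulated pairs of unchanged groups that share the [isp-] arrays. The simulation gave every array the spread pooled over the 3 strains. The [isp-] arrays were tighter, with SDs from the rest of their strain of 0.19 to 0.22 against 0.87 for sfp1delta replicate 3. The 0.026 is thus likely too high for what sharing the [isp-] arrays adds. With the [isp-] arrays split so that each comparison had its own pair, the correlation off II and IX was -0.06 and -0.15. In these 2 splits 189 and 172 genes off II and IX rose in both (236.7 and 243.3 for independent lists), 30 and 30 fell in both (43.0 and 64.2), and 319 and 542 went opposite ways (202.9 and 250.2). Over all genes, 1075 changed in the same direction and 1106 in opposite directions without sfp1delta replicate 3, against 560 and 396 with every array. Without [isp-] replicate 1 or 2 or [ISP+] replicate 3 the opposite changes over all genes numbered 259, 247 and 263.

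**Figure D4:**
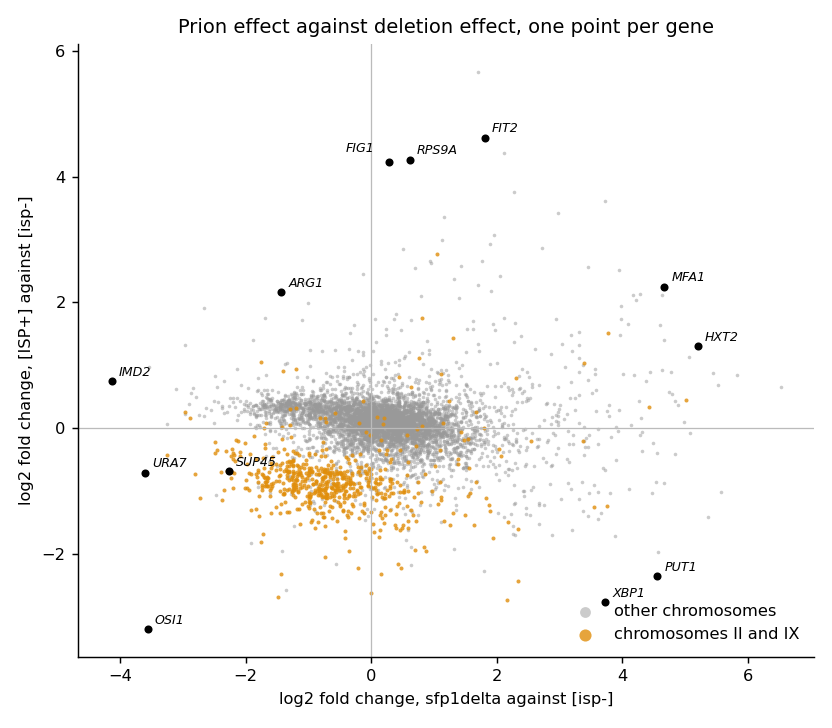
Log2 fold change in [ISP+] against that in sfp1delta, both relative to [isp-], with a point for each gene except SFP1 and the genes of chromosomes II and IX in orange. Genes of II and IX lie lower on both axes, with relative medians of -0.98 and -0.94 in [ISP+], and over the other genes the correlation is -0.08.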

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

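The tests of the slide for the chromosomes, of a mislabelled array, of alpha-specific genes and of a state of the [isp-] arrays, and the settings that leave out or re-centre chromosomes, were chosen only after the results were seen.

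Genes of chromosomes II and IX had lower signal in [ISP+] and in sfp1delta than in [isp-]. The slide argues against itself as the source, since the weakest of the 8 values within slides was -0.76, and so does a bias that depends on signal, since genes of other chromosomes matched on signal had a relative median of 0.012. A candidate explanation is that the [isp-] cultures carried 2 copies of both chromosomes for each copy in the other strains, which needs a value near -1 on every arm, and in [ISP+] the arm farthest from it had -0.92. The right arm of IX in sfp1delta had -0.50, and DNA was not measured, so copy number itself stays open. With the genes of both chromosomes left out 675 genes were called in [ISP+], and with each chromosome's median removed 732 were.

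Replicate 3 of sfp1delta lay apart from the other 3 sfp1delta arrays in 10 of the 16 values that stood out among 114 groups of 4 arrays, where chance alone would single out about 1 in 20. Relative to the [isp-] mean its list medians were -2.58 for ribosomal proteins (others -1.005 to -0.90), -1.51 for translation factors (-1.07 to -0.99), -1.07 for Gcn4 genes (-0.64 to -0.61), -1.76 for purine genes (-1.03 to -0.97), -1.04 for glycolysis (-0.22 to -0.11), 0.31 for the TCA cycle (1.13 to 1.19), 3.37 for glucose-repressed genes (2.15 to 2.23), 2.37 for hexose transport (1.6004 to 1.7145) and -0.35 for ergosterol (0.19 to 0.26), and its SUP35 level was 1.41 (0.49 to 0.58). Transcript length is argued against as the whole cause. The deviation correlated with gene length (rho 0.53), with medians of -0.63 in genes of up to 765 bases and 0.55 in genes of 1911 bases or more. Its SD fell only from 0.84 to 0.72 once the trend was removed, against 0.37 at most for another sfp1delta array. Each array was set against the mean of the other 3 of its strain, so replicate 3 enters the values of the other sfp1delta arrays. The rho of -0.57 for sfp1delta replicate 2 is thus at least partly the mirror image of replicate 3, and the 0.37 is raised in the same way. In [ISP+] the rho was -0.54 for replicate 1 and 0.51 for replicate 2, which depend on each other likewise. A wrong strain label is argued against by SFP1, which lay at -6.89 relative to [isp-]. A stronger form of the deletion effect stays open, since the deviation correlated with the deletion effect at 0.24. A difference in the RNA of this culture may remain, which no value here tests.

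Mating and pheromone response genes were higher in [ISP+] than in [isp-]. The slide is argued against by list medians, relative to all genes, of 0.57 within the slide of 8 arrays and 0.72 within the other, which has 1 array of each of these strains. Cells of the other mating type in the [ISP+] cultures are a candidate explanation, as the 4 alpha-specific genes had a median of 1.18, but STE3, MF(ALPHA)1 and MF(ALPHA)2 were not well above background on all arrays and SAG1 went from -4.05 to -3.32. MATALPHA1 was not called (-4.39 and -4.27, adjusted p = 0.687), STE3 was at least 33.2-fold higher in sfp1delta than in [isp-], and a-specific MFA1 at 2.25 and AGA2 at 1.57 rose as well while BAR1 did not (0.07, adjusted p = 0.721). A state of the [isp-] arrays is a further one, since the list also rose in sfp1delta. Camera did not call the list between [ISP+] and sfp1delta (adjusted p = 0.0908), but a missed threshold does not show equal levels. Without sfp1delta replicate 3 camera called it (adjusted p = 0.0372). With all arrays, fry's directional test, which asks only about the list's own genes, called it higher in [ISP+] than in sfp1delta (adjusted p = 0.00318).

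The remaining values that stood out came from single arrays of other strains. SUP45 lay at 2.28 on [isp-] replicate 3 (others 2.21 to 2.22). SUP35 lay at 1.32 on [ISP+] replicate 1 (others 1.71 to 1.77). On the same array the iron list lay at 0.61 (others 1.02 to 1.05). The purine list lay at 0.29 on [ISP+] replicate 3 (others 0.37 to 0.38). On [ISP+] replicate 2 the glucose-repressed list lay at -0.28 (others -0.20 to -0.19) and the cell cycle list at 0.074 (others -0.06 to -0.04).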

How the results depend on the processing

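Leaving out chromosomes II and IX, removing chromosome medians and removing the length trend were chosen only after the results were seen. Over 562 results and 37 settings, 18554 of 19478 values counted as the same: for genes and lists the same direction and side of the threshold, or no call in either fit; for counts within 1.5 times; for chromosome shifts within the spread between arrays; of 454 values of named genes 265 did so in every setting, and of 87 list values 28 did. As few as 89.6% of an array's probes were well above background, so some folds of dim genes are only bounds. The cause was not tested for the changes below unless it is stated.

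Scaling moved the balance of rises and falls. The median change of all genes was 0.16, 0.07 and -0.14 in the deletion, prion and difference comparisons, and it became 0.88, -0.15 and -1.09 with spike-in centring and -0.02, 0.07 and 0.03 with quantile normalization. Rises made up 59.6% of deletion calls, against 47.0% (quantile), 51.3% (array median), 91.9% (spike-in), 47.8% (normexp) and 47.5% (the authors' values). For the difference they made up 41.1%, against 53.0%, 49.0%, 7.21%, 52.6% and 52.7% in the same order, and for the prion 38.1%, against 17.0% with spike-ins.

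Chromosome shifts were smaller after quantile normalization (-0.91 for II in the deletion, -0.94 for II and -0.90 for IX in the prion comparison), normexp (-0.83, -0.70, -0.86 and -0.83 for II and IX in the deletion and then the prion) and in the authors' values (-0.85, -0.71, -0.89 and -0.86). Within the slide of 8 arrays II had -1.02 in the deletion, and within the slide of 4 the prion values were -0.95 and -0.92. The prion ribosomal protein median was 0.167, 0.152 and 0.164 and not called under quantile, normexp and the authors' values (adjusted p = 0.162, 0.163 and 0.163), and 0.350 without A or B copies (adjusted p = 0.122), where fewer genes remain; over all settings adjusted p ran from 1.8e-09 to 0.884. With spike-in centring 276 prion genes were called (47 up, 229 down), with 61 same and 92 opposite changes in both comparisons.

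Counts also depended on the fit. The prion count was 730 within the slide of 8 arrays with 346 same and 163 opposite changes; 2906 in a fit to the 2 strains alone, which leaves the sfp1delta arrays out of the error, with 946 opposite changes; and 3384 with array weights, with 1342 and 1389. A threshold of 0.01 gave 767, 352 and 167, and a 2-fold minimum gave 1560 deletion, 375 prion and 1798 difference calls with 96 and 66, as stricter thresholds must. Leaving out the genes of II and IX gave 675 prion calls and 209 same changes, and removing chromosome medians gave 732 and 225. With an estimated correlation, 0, 1 and 0 lists were called, and among those lost were ribosomal proteins (-1.37, 0.35 and 1.72) and ribosome biogenesis (-1.16, 0.32 and 1.45). In fry's directional test of the prion comparison ribosomal proteins were not called (adjusted p = 0.497). Ribosome biogenesis (adjusted p = 0.0217), iron (6.93e-04) and mating genes (1.4e-08) were called there.

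Directions reversed for few results. In the difference comparison OLI1, at 0.45, became -0.270, -0.274 and -0.275 under quantile, normexp and the authors' values, and the glycolysis list, with medians of 0.047, 0.011 and 0.032, had its test reversed. Spike-in centring turned SUP35 (0.053) and DUS4 (0.177) in the deletion, and SUP35 (-0.076), DUS4 (-0.151), ERG24 (-0.011), NCP1 (-0.399) and ERG7 (-0.458) in the difference. SEI1 became -0.177 in the deletion with the authors' values. Removing chromosome medians, which takes out the shift of II and IX by construction, turned LYS2 in the deletion (0.021) and, in the prion comparison, SUP45 (0.176), UTP25 (0.121), REI1 (0.151), TAE1 (0.013), GRS1 (0.389), HTB2 (0.127), PAU15 (0.259), BCY1 (0.025), HIS7 (0.167) and LYS2 (0.418).

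With each array left out in turn, the deletion count ran from 3336 to 4295, the prion count from 968 to 2733 and the difference count from 3454 to 4333, and SFP1 in the deletion from -8.14 to -7.28. Prion shifts ran from -0.996 to -0.964 for II and -0.962 to -0.931 for IX. Changes in both comparisons numbered 448 to 1075 in the same direction and 247 to 1106 in opposite directions. The highest counts came without sfp1delta replicate 3.

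The clone numbers do not pair the arrays: correlations of same-numbered deviations over 12 pairs ran from -0.324 to 0.363, with 4 over 0.1, and 4 arrays correlated best with their own number. With the replicate block the counts were 3583, 1144 and 3728.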

Other observations

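RPS9A went from -1.72 in [isp-] to 2.55 in [ISP+], and its copy RPS9B lay at 5.09 in [isp-], 3.41 in sfp1delta and 5.16 in [ISP+] (-1.68 in the deletion, adjusted p = 3.13e-04; 0.07 in [ISP+], adjusted p = 0.891). RPS9B lies on chromosome II, whose genes had a median of -0.74 in sfp1delta and -0.88 in [ISP+]. Off chromosomes II and IX fewer genes fell in both strains than for independent lists (41 against 65.8). Those that did include OSI1, the methylglyoxal reductase gene GRE2 (-1.91 in sfp1delta and -1.84 in [ISP+]), IZH4 (-2.46 and -1.06) and RTA1 (-1.22 and -1.56). The glutathione transferase genes ECM4 (-1.63) and GTT2 (-1.79) were lower in [ISP+]. The aromatic aminotransferase gene ARO9 (-1.80 and -0.94) and the decarboxylase gene ARO10 (-1.28 and -1.06), both of amino acid catabolism, were lower in both. SIR2, the deacetylase of silent chromatin, rose by 1.08 in [ISP+] (adjusted p = 1.8e-05). These genes were singled out after their values were seen.

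Lists that the account above leaves aside went several ways, and calls of lists here are camera's at its preset correlation. In fry's directional test, termination genes were lower in the deletion (adjusted p = 2.1e-04) and higher in the difference (7.01e-05). Regulators of ribosomal genes were higher in the deletion and lower in the difference (0.00826 and 0.00254). Phosphate genes were lower in [ISP+] and in the difference (0.0203 and 8.98e-04), and prion proteins and modifiers were lower in the deletion (0.029). Termination and nonsense-mediated decay genes were not called (deletion median -0.03, adjusted p = 0.117; prion median 0.07, adjusted p = 0.866; difference median 0.35, adjusted p = 0.0674), with 7 falls and 2 rises among 17 in the deletion, also adjusted over the list alone, and a mean of -0.29. Histone genes were not called either (0.06, -0.11 and -0.12, adjusted p = 0.891, 0.616 and 0.776), but after quantile normalization they rose in the deletion (0.51, adjusted p = 0.0305) and were lower in the difference (-0.84, adjusted p = 0.00294). Of the 11 histone genes 4 lie on II and IX, with the 2 falls of the deletion, and off these chromosomes the deletion median was 0.56, with 4 rises and 0 falls (adjusted p = 0.33). Of 29 cell cycle genes 9 rose and 8 fell in the deletion, where CLB6 changed by -3.25 and SIC1, an inhibitor of cyclin-dependent kinase, rose by 1.04, and 0 rose and 2 fell in [ISP+], the same adjusted over the list alone (medians 0.09, -0.02 and -0.22, adjusted p = 0.65, 0.516 and 0.84; the deletion mean was -0.02). Regulators of ribosomal genes rose in 19 of 33 cases and fell in 5 in the deletion, also adjusted over the list alone (median 0.38, adjusted p = 0.167), with CRF1 at 2.23, and had medians of 0.01 in [ISP+] (mean -0.09, adjusted p = 0.516) and -0.42 in the difference (adjusted p = 0.139).

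Of 33 methionine and sulphate genes 13 rose and 10 fell in the deletion, or 14 and 10 adjusted over the list alone (median 0.16 with a downward test, adjusted p = 0.856), with CYS4 at -1.74 and the sulphate permease gene SUL2 at 1.41, and the medians were 0.08 and -0.20 in the prion and difference comparisons (adjusted p = 0.87 and 0.98). Of 19 phosphate genes 8 rose and 4 fell, also adjusted over the list alone (median 0.41, adjusted p = 0.856), with the acid phosphatase gene PHO11 at -1.76 and PHM6 at 2.27. In [ISP+] they had a median of -0.33 (adjusted p = 0.182) and in the difference -0.17 (adjusted p = 0.778), where GPP2, a glycerol phosphatase that does not serve phosphate uptake, lay at -2.66. Off II and IX the [ISP+] medians were 0.25 for methionine and -0.20 for phosphate genes, and the difference median of termination genes was 0.19. Prion proteins and modifiers were not called (medians 0.04, 0.03 and -0.16, means -0.45, -0.05 and 0.40, adjusted p = 0.336, 0.866 and 0.54), with 6 rises and 7 falls among 20 in the deletion, also adjusted over the list alone, a median of 0.15 off II and IX, and VTS1 at -1.31. Genes of the mitochondrial genome were not called (medians -0.33, -0.37 and -0.02, adjusted p = 0.248, 0.109 and 0.818), though in [ISP+] they were after quantile normalization (adjusted p = 0.0308) and without [isp-] replicate 4 (median -0.54, adjusted p = 0.0397). Nutritional marker genes fell in the deletion (median -0.73, adjusted p = 0.0191, and adjusted p = 0.202 with an estimated correlation; 2 up and 6 down, or 2 and 6 adjusted over the list alone) and were higher in the difference (median 0.58, adjusted p = 0.0112, and adjusted p = 0.16 with an estimated correlation; 7 up and 2 down, or 7 and 2 adjusted over the list alone), calls lost after quantile normalization (adjusted p = 0.0918 and 0.0503). Off II and IX the deletion median of the markers was -0.44 and the list was not called (adjusted p = 0.0645). They were not called in [ISP+] (median 0.25, adjusted p = 0.711); HIS3 changed by -2.08 and MET17 by -1.61 in the deletion.

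Several calls were weak. Mitochondrial ribosomal protein genes shifted little in the deletion (median -0.09, adjusted p = 0.0299, and adjusted p = 0.772 with an estimated correlation; 8 up and 16 down, or 8 and 16 adjusted over the list alone; 0.07 and adjusted p = 0.276 without sfp1delta replicate 3, and -0.17 without replicate 2) and in [ISP+] (median -0.06, adjusted p = 0.0113, and adjusted p = 0.831 with an estimated correlation; 0 up and 7 down, or 0 and 7 adjusted over the list alone; -0.11 without [ISP+] replicate 1 and -0.03 without replicate 3), where all 7 falls were on II and IX. Off II and IX these medians were -0.04, not called (adjusted p = 0.0632), and -0.03. The list was not called in the difference (median 0.04, mean -0.01, adjusted p = 0.516), where MRP8 and KGD4, which are not structural proteins of that ribosome, lay at -1.26 and -1.16. In [ISP+] the glucose-repressed list (median -0.19, adjusted p = 0.0466, and adjusted p = 0.798 with an estimated correlation; 4 up and 10 down, or 6 and 11 adjusted over the list alone) lost its call without [isp-] replicate 1, 2 or 3 or [ISP+] replicate 2 or 3, with adjusted p of up to 0.0714. The sporulation list (median -0.12, adjusted p = 0.0413, and adjusted p = 0.607 with an estimated correlation; 0 up and 8 down, or 0 and 9 adjusted over the list alone) lost it without [isp-] replicate 1 or 3, sfp1delta replicate 3 or [ISP+] replicate 3, with adjusted p of at least 0.0506, and the seripauperin and COS list (median -0.19, adjusted p = 0.0393, and adjusted p = 0.61 with an estimated correlation; 3 up and 6 down, or 3 and 7 adjusted over the list alone) without [isp-] replicate 1 (0.0761) or [ISP+] replicate 3 (0.0646). Off II and IX the sporulation median was -0.07, and the glucose-repressed list had 4 rises and 5 falls in [ISP+]. With the slide as a random block these 3 had adjusted p of 0.188, 0.0895 and 0.26. Glycolytic genes in [ISP+] (median 0.35, adjusted p = 0.0113, and adjusted p = 0.607 with an estimated correlation, with 4 up and 0 down, or 2 and 0 adjusted over the list alone) lost the call after quantile normalization (adjusted p = 0.162) and with II and IX left out (adjusted p = 0.076). In the difference (median 0.73, adjusted p = 0.00594, and adjusted p = 0.369 with an estimated correlation, with 16 up and 4 down, or 17 and 4 adjusted over the list alone) they lost it with the slide as a random block (adjusted p = 0.057). Quantile normalization, normexp and the authors' values also lost the difference call and reversed its direction (medians 0.047, 0.011 and 0.032, adjusted p = 0.966, 0.919 and 0.921). Translation factors in [ISP+] (median 0.27, adjusted p = 0.00192, and adjusted p = 0.607 with an estimated correlation; 4 up and 0 down, or 4 and 0 adjusted over the list alone) lost it after quantile normalization (adjusted p = 0.0523), and the polymerase list was not called there (median 0.23, adjusted p = 0.188; 4 up and 3 down, or 4 and 3 adjusted over the list alone). Ergosterol genes were not called in the deletion (median 0.04, adjusted p = 0.891; 8 up and 1 down, or 1 and 0 adjusted over the list alone) and were higher in the difference (median 0.33, adjusted p = 0.0131, and adjusted p = 0.604 with an estimated correlation; 10 up and 1 down, or 10 and 1 adjusted over the list alone; adjusted p = 0.0531 without sfp1delta replicate 3 and a median of -0.55 with spike-ins). Chaperone and proteasome genes were not called in the difference (chaperones median 0.12, adjusted p = 0.336; 17 up and 15 down, or 17 and 16 adjusted over the list alone, with a mean of -0.14; proteasome median -0.07, adjusted p = 0.776; 0 up and 6 down, or 0 and 5 adjusted over the list alone, and a median of -0.17 without sfp1delta replicate 3).

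For each comparison the 35 ways of splitting its 8 arrays into groups of 4 were fitted, with the 4 arrays of the third strain kept in the fit as in the main one, and only 1, the real one, gave as many genes. The deletion split called 3677 genes against 3 for the highest other, the prion split 1284 against 1 and the difference split 3785 against 118. Every other split puts arrays of both strains in both groups, which shrinks the contrast and widens the error. Lower counts there follow from the strains lying apart, so these counts cannot exclude chance.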
